A study of Homo sapiens with 2 samples.

How the data were processed

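The series holds 2 chromatin immunoprecipitation libraries for acetylated lysine 27 of histone H3 (H3K27ac), a mark of active promoters and enhancers. Both come from F36P, an established human erythroid leukaemia cell line. 1 library came from cells transduced with a retroviral vector that carries ERG, an ETS-family transcription factor, and 1 from cells transduced with the empty vector. They are called the ERG library and the Vector library below. The title of the ERG library reads AM-ERG, and the meaning of AM was not established here. Per the labels, cells were selected with puromycin at 1 µg/ml for 4 days before the assay. Chromatin was fixed with 1% formaldehyde, cut with micrococcal nuclease, and 10 µg of it was used per pull-down, per the labels' protocols.

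The submitters' processing notes name Bowtie2, MACS2, deepTools and the hg38 build, without versions or settings. Each deposited file is a peak list of 10 columns for a single library, so peaks are per library and not pooled. Whether an input library was used, and how duplicate or poorly mapped reads were treated, is not given in the sources used here. The lists give each peak's position, its summit, and 4 values that are the authors' own. The deposited fold is the enrichment at the summit over the local background. That background comes from the same library only if no input library was used. The deposited −log10 p-value and −log10 q-value are those of the peak caller at the summit. The lowest deposited −log10 q-value was 1.31 in the ERG library and 1.32 in the Vector library, which is a q-value threshold of 0.05. The deposited score equals 10 times the −log10 q-value, cut to a whole number, in all but 9 ERG-library peaks and 1 Vector-library peak. These values were used to rank or filter peaks within their own list.

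Read totals are not part of a peak list. MACS2 computes its fold as the fragments at the summit plus 1 over the local background plus 1, and its p-value as a Poisson tail, so the deposited fold and −log10 p-value together fix both the number of fragments and the background. That number came out whole for 19650 of 19671 ERG-library peaks (99.9%) and 9150 of 9161 Vector-library peaks (99.9%), with a relative error of the recomputed −log10 p-value below 0.0001. The lowest background, which is the level of the whole genome, was 2.31 fragments in the ERG library and 1.60 in the Vector library. Their ratio of 1.44 was used as the relative depth. The narrowest peaks were 294 and 288 bp wide. In a test on simulated data with 3000 peaks of each library, 100% of the fragment numbers were recovered. The simulated values were made with the same formulas. The test therefore covers the calculation, not whether these formulas hold for the deposited lists.

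Genes were taken from the RefSeq table of GRCh38.p14, which shares its chromosome coordinates with hg38. It lists 20037 protein-coding genes on chromosomes 1 to 22, X and Y. This table gives the start and end of each gene without strand, transcription start sites or exons. The planned promoter window around start sites was therefore replaced by a window of 1 kb either side of both ends of each gene record, called the gene ends. Exon, intron and UTR positions are not reported for the same reason. Sequence motifs, planned before the data were examined, were not analysed here, since no genome sequence was used. An alternative with a single start site per gene was not run, because strand was not used.

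A peak was called shared when it overlapped a peak of the other list by at least 1 bp. As a chance level, the Vector-library peaks were moved along their chromosomes 100 times by random distances. Shares are given with exact (Clopper-Pearson) 95% binomial intervals, and ratios of 2 fragment numbers with exact conditional 95% intervals. All of these cover counting error only. With 1 library per group there is no spread between samples, so no test between the groups was made and no p-value is given. Every difference below compares these 2 libraries, not the conditions.

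Gene lists, 23 in number, were fixed before the data were examined, together with the choice of overlap, windows and alternatives. They cover erythroid, other blood, endothelial and regulatory genes, ribosomal protein genes as a control of open promoters, and liver, neuron, epithelial and fibroblast genes as controls of silent genes. Of 519 listed names, 518 matched the gene table. For each list, the members with a gene-end peak were counted. The length covered by peaks within 50 kb of either gene end, so not over the whole of a long gene, was also measured, and the list median of the difference (ERG minus Vector library) was set among the medians of 10000 random lists of the same size. These were matched in 20 bins of mean covered length. The resulting percentile describes these libraries, and 1.15 of 23 lists would lie below 2.5 or above 97.5 by chance. This figure includes tied lists, the stem and progenitor list and the silent controls. Their median and that of their random lists were both 0, which gave percentile 50, so they could hardly lie outside. Peaks away from gene ends were joined into domains when 12.5 kb or less apart and ranked by covered length.

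The genes named were chosen by a rule written beforehand. They are ERG and HDAC7. They are also, per list, up to 4 members with a gene-end peak in the ERG library alone and up to 4 in the Vector library alone, by size of the covered-length difference, or otherwise the 2 members with the largest difference. Then come the 10 genes with the largest excess of covered length in each library, left out if within 100 kb of one already taken. The last are the genes nearest the 5 top-scoring unshared peaks and the 10 domains of largest covered length of each library. Other genes named were chosen after their values were seen, as said where they appear. Some genes and peaks that the rule takes are not reported here.

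A comparison of fragment numbers at shared peaks was added after the data were seen, and stands in the closing section. It took, for each gene, the shared peak at its ends with the most fragments, and the log2 ratio of fragments (ERG over Vector) relative to the median of all shared peaks. Lists of 5 or more such genes were set among random lists matched on fragment number. In simulated data on 6023 genes, 20 of 20 lists of 10 genes with a true fold of 0.5 lay below the 2.5 percentile and 0 of 20 unchanged lists did. Both simulated libraries held counting error alone around 1 common ratio, with no added spread between genes. The fold of 0.5 was also stronger than the median of 0.684 relative to the typical shared peak in the heme list. The simulation therefore does not show how reliably the real lists are called.

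The alternatives were the upper 50% of each list by score, peaks within 1 kb joined, other overlap rules, an ERG list limited to the length of the Vector list, peaks reduced to 500 bp, windows of 2.5, 10 and 100 kb, peak numbers in place of covered length, and a stitching distance of 5 kb. Added later were versions of the ERG list in which each summit's fragments and background were thinned at random. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.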

Results

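Peaks of H3K27ac were compared between an ERG library and a Vector library of F36P erythroid leukaemia cells, to ask how raised ERG relates to histone acetylation in cells whose erythroid differentiation ERG is reported to inhibit. Each group held 1 library. The ERG library had 19671 peaks covering 15.0 Mb and the Vector library 9161 peaks covering 5.30 Mb. The ERG library was the deeper of the pair, with a genome background of 2.31 fragments against 1.60, a ratio of 1.44. No replicate check of any difference was possible, and the intervals cover counting error only.

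The acetylated sites of the Vector library were nearly all found again in the ERG library, which added many more. Of the 9161 Vector-library peaks, 8339 overlapped an ERG-library peak, 91.0% (95% interval 90.4 to 91.6). After random shifts along the chromosomes a mean of 1.14% did so. Of the 19671 ERG-library peaks, 11579 had no Vector-library peak, 58.9% (58.2 to 59.6), whereas 822 Vector-library peaks had no ERG-library peak, 8.97% (8.40 to 9.58). The unshared ERG-library peaks were narrower than the shared ones, with median widths of 486 and 946 bp, and the unshared Vector-library peaks were narrower still, at 331 bp. The ERG list was the longer one on every chromosome, from 1.69 times on chromosome Y to 2.66 times on chromosome X. With the ERG list limited to its 9161 top-scoring peaks, the unshared shares were 28.5% and 25.8%, which lists of equal length bring close together by construction. With the ERG library thinned to the Vector background they were 55.7% and 9.99%, and thinned by the ratio at strong shared peaks 47.0% and 16.7%. Whether an ERG-library peak had a counterpart followed its strength, from 8.79% (7.85 to 9.80) of peaks with fewer than 20 fragments at the summit to 93.2% (91.8 to 94.4) of those with 100 or more.

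In the full lists, shared sites lay mainly at gene ends, and the sites of the ERG library alone mainly away from them. On chromosomes 1 to 22, X and Y, 66.0% (64.9 to 67.0) of the shared ERG-library peaks lay within 1 kb of an end of a protein-coding gene. The share was 29.4% (28.6 to 30.3) among ERG-library peaks with no Vector-library counterpart. Of the latter, 36.9% lay elsewhere inside a protein-coding gene and 33.7% between such genes. The unshared Vector-library peaks had the lowest share at gene ends, 14.5% (12.1 to 17.1), and 18.6% (16.0 to 21.5) of them lay farther than 500 kb from any protein-coding gene, against 8.20% (7.61 to 8.82) of the shared Vector-library peaks. In the upper 50% of each list by score, the share at gene ends was 53.5% for unshared ERG-library peaks, 36.3% for unshared Vector-library peaks and 72.4% for shared peaks. Most unshared ERG-library peaks of that setting thus lay at gene ends, though still a lower share than of shared peaks.

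**Figure D1:**
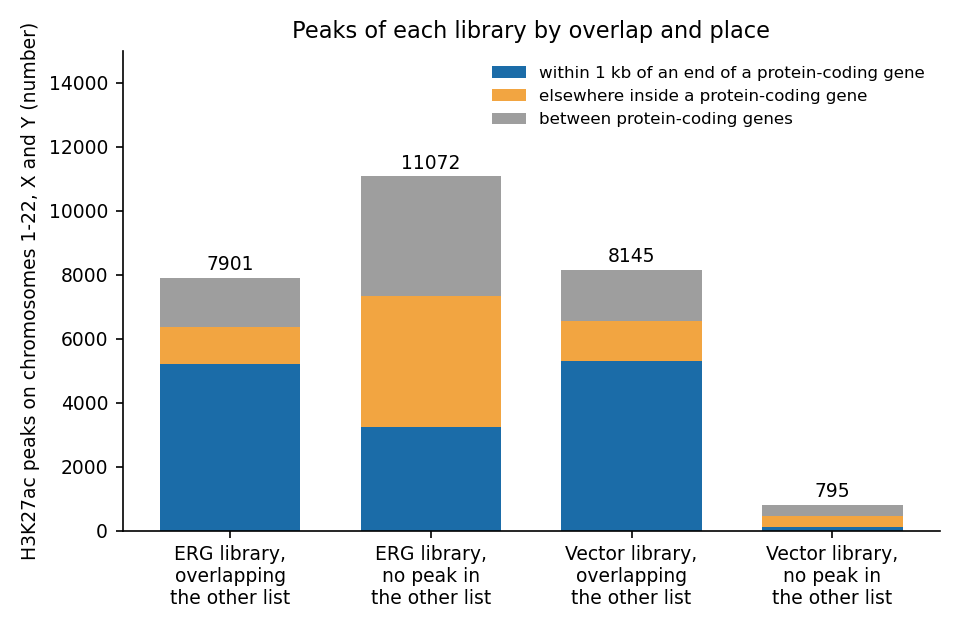
Number of H3K27ac peaks on chromosomes 1 to 22, X and Y in each library, split by overlap with the other list and coloured by place relative to protein-coding genes. The 11072 unshared ERG-library peaks form the tallest bar and lie mostly away from gene ends, while 5211 of the 7901 shared ERG-library peaks are within 1 kb of one.

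The gene ERG itself, on chromosome 21 from 38367261 to 38661783 (hg38), had 6 ERG-library peaks inside it or within 50 kb, against 1 Vector-library peak. The peak at 38376522 to 38376857 of the Vector library, inside the gene, overlapped a wider ERG-library peak at 38375745 to 38377820. The other 5 were in the ERG library alone, 3 inside the gene (38383522 to 38384370, 38475491 to 38477358 and 38497639 to 38498204) and 2 outside it at 9.98 and 11.6 kb (38356310 to 38357284 and 38355156 to 38355686). No peak of either library lay within 1 kb of an end of ERG. Exon positions were not used here, so fragments of the introduced ERG sequence could not be told from those of the resident gene.

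HDAC7, the class IIa histone deacetylase of the series title, lies on chromosome 12 from 47782722 to 47821344. It had 5 ERG-library and 4 Vector-library peaks inside it or within 50 kb, and a covered length of 5965 against 3788 bp. All 4 Vector-library peaks, on either side of the gene, overlapped ERG-library peaks. Of these peaks, 3 of the ERG library and 2 of the Vector library lay inside the neighbouring heme transporter gene SLC48A1 (47753934 to 47782751), so they cannot be assigned to HDAC7. A peak inside the gene, at 47819364 to 47819705 and 1639 bp from its nearer end, was found in the ERG library alone, as was one at 47759191 to 47759589 inside SLC48A1. Neither library had a peak within 1 kb of the ends of HDAC7. With a window of 2.5 kb the gene counted as having a peak in the ERG library alone.

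**Figure D2:**
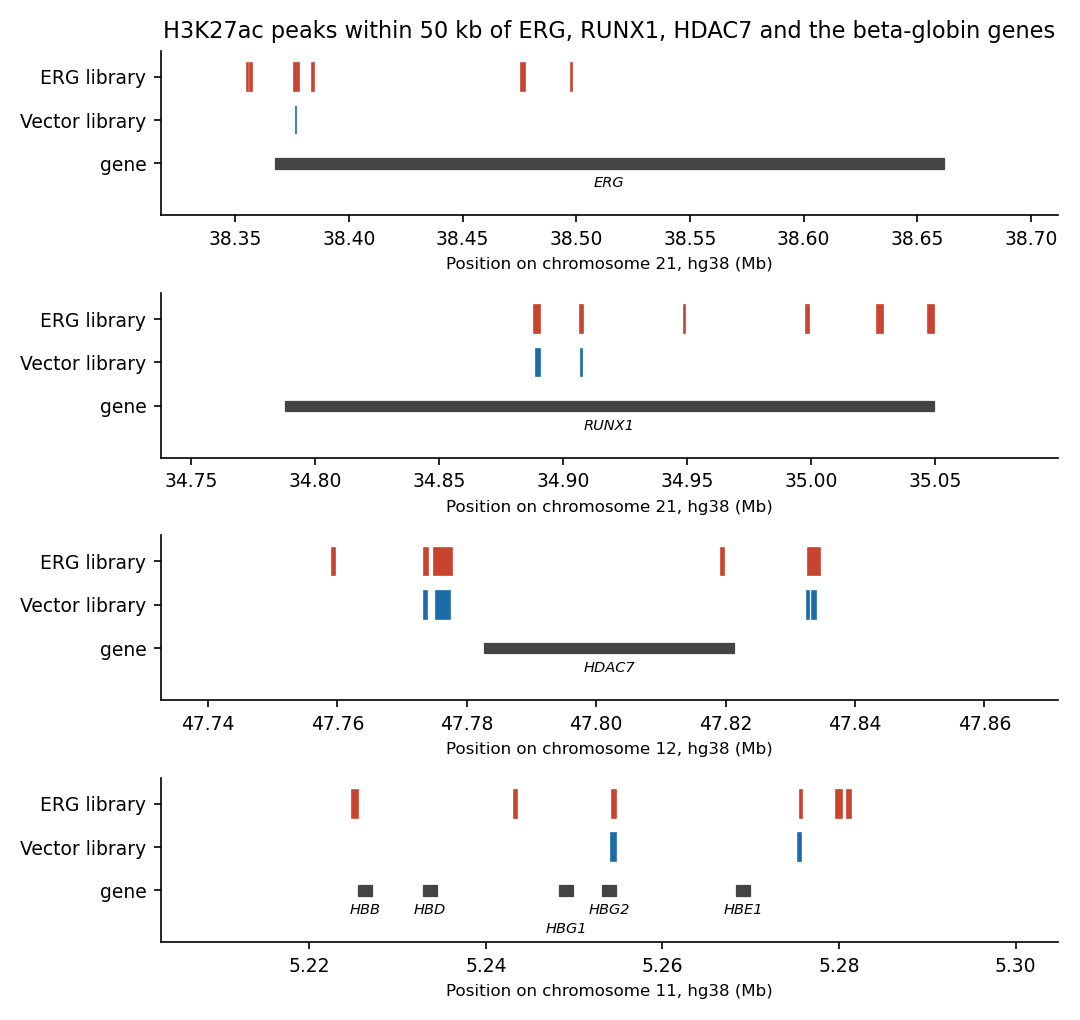
Positions of H3K27ac peaks (Mb, hg38) of the ERG library (red) and the Vector library (blue) from 50 kb before to 50 kb after ERG, RUNX1, HDAC7 and HBG2, with gene records in grey and the other beta-globin genes drawn beside HBG2. ERG has 6 peaks against 1, RUNX1 10 against 2, HDAC7 5 against 4 and the HBG2 window 6 against 2, and some neighbouring peaks merge at this scale.

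Over all 20037 protein-coding genes, 6049 had a gene-end peak in both libraries, 3131 in the ERG library alone, 71 in the Vector library alone and 10786 in neither. The ERG library thus had a peak at 22.5% of the 13917 genes that lacked one in the Vector library. With the ERG list limited to the length of the Vector list, which by construction brings the counts closer, 1235 genes had a peak in the ERG library alone and 734 in the Vector library alone.

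All but 1 of the listed erythroid genes with an end peak in the Vector library also had one in the ERG library, as did all but 1.16% of the 6120 genes of the whole set with a Vector-library end peak. Of 18 heme synthesis and transport genes, 14 had an end peak in both libraries, among them FECH, PPOX and CPOX of the heme pathway (chosen after their values were seen). 1 had it in the ERG library alone, ALAS2, the erythroid form of the first enzyme of heme synthesis. Among 10 globin genes, HBB, the adult beta-globin gene, had an end peak in the ERG library alone, and HBG2 and HBQ1 had one in both. The HBB peak, at 5224793 to 5225467 on chromosome 11, lay at the lower-coordinate end of the gene record (5225464 to 5227071). Neither library had a peak within 1 kb of the other end. Strand was not used, so the HBB peak cannot be called a promoter peak. HBG2 is nearly identical to HBG1, so its reads are uncertain. Of 21 erythroid transcription regulators, 14 had an end peak in both libraries, and LMO2, KLF13 and HES6 in the ERG library alone. GATA1, the central erythroid factor, counted as both through 2 peaks that did not overlap, at 48786613 to 48787215 on chromosome X in the Vector library and 48787375 to 48787937 in the ERG library. Of the 14 regulators, 12 had a shared end peak with recovered fragments, and ZBTB7A was the other one without it. GATA1 and ZBTB7A were singled out after their values were seen. Among 29 membrane and blood group genes, 13 had a peak in both and 4 in the ERG library alone, ICAM4, CD36 and the near-identical pair GYPB and GYPE. Of 16 iron genes, 11 had a peak in both. STEAP3, an iron reductase gene, was the single member of all 23 lists with an end peak in the Vector library alone, 404 bp covered against 0. In the erythropoietin and cytokine signalling list, 14 of 20 had a peak in both and OSM, SOCS3 and ERFE in the ERG library alone. Of members without a Vector-library peak, the ERG library had one at 1 of 8 in the globin list, 1 of 4 each in the heme and iron lists, 4 of 16 in the membrane list, 3 of 7 among the transcription regulators and 3 of 6 in the signalling list. The counting interval of each share included the 22.5% of all genes.

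Of 30 myeloid genes, 3 had an end peak in both libraries and 9 in the ERG library alone, which is 33.3% (16.5 to 54.0) of those without a Vector-library peak. These 9 included FCER1G, GFI1, MS4A3 and CD33. For 30 megakaryocyte and platelet genes the counts were 3 and 4, the latter ITGB3, ANGPT1, PEAR1 and F2R. PEAR1 counted as both with a 2.5 kb window. For 31 stem and progenitor genes they were 3 and 4, the latter BMI1, TRIB1, TRIB2 and MLLT3. In the 26 endothelial genes, a programme in which ERG is known to act, 1 had an end peak in both and ENG, TIE1, PECAM1 and ICAM2 in the ERG library alone. The mast cell list had 2 of 13 in both and CPA3 in the ERG library alone, and the lymphoid list 1 of 24 in both and CD79A in the ERG library alone. None of these shares lay outside 22.5% by more than its counting interval except that of the lymphoid list, 4.35% (0.110 to 21.9).

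The heptad, a set of 7 blood stem cell transcription factors that includes ERG, had a larger excess of covered length in the ERG library than matched random lists. Of its genes 3 had an end peak in both libraries and 2 in the ERG library alone. Its median difference in covered length within 50 kb was 4203 bp, at percentile 99.7 of random lists, whose median was 2481 bp, and all 7 members were covered over a greater length in the ERG library. The same held for all 48 ribosomal protein, all 27 corepressor and coactivator and all 18 heme genes, though for only 9 of 20 liver genes. A greater length in every member therefore does not set the heptad apart. Within 50 kb of its ends, RUNX1 had 4203 bp covered against 0, its 2 Vector-library peaks lying deeper inside the gene, and LMO2 had 4529 against 1730 bp, and both had the gene-end peak in the ERG library alone. FLI1 was covered over 5006 against 487 bp and TAL1 over 7912 against 2129 bp, both chosen after their values were seen. The mast cell list (1415 bp, percentile 99.8) and the endothelial list (1072.5 bp against 499 bp in random lists, percentile 98.5) also lay above the central 95% of random lists, where 1.15 of 23 lists, tied lists included, would lie outside by chance. The heptad lay at percentiles 96.7, 93.1 and 93.8 with a 10 kb window, the upper 50% by score and the shortened ERG list, respectively. The mast cell list lay inside the central 95% under 4 of 5 alternatives and the endothelial list under all 5.

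**Figure D3:**
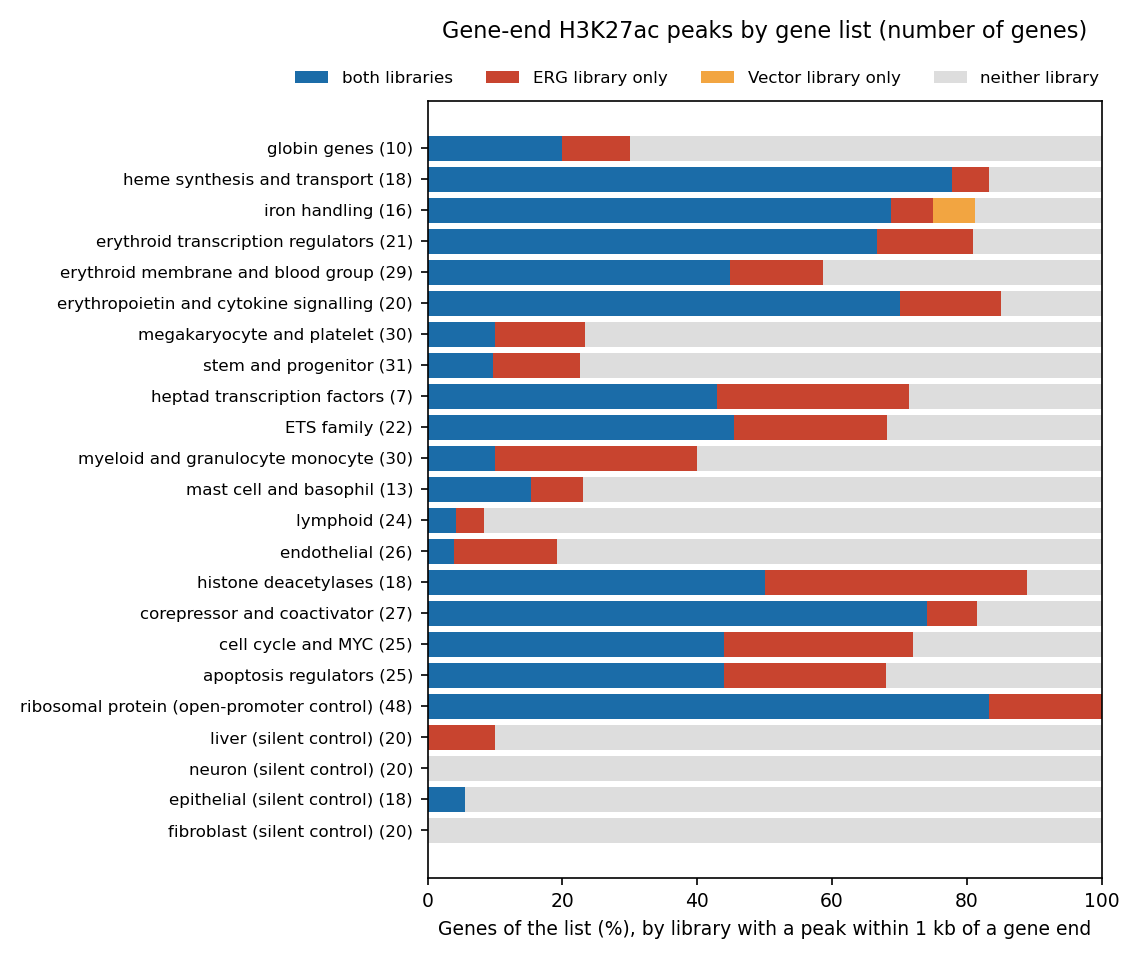
Share of the genes of each list (%) with an H3K27ac peak within 1 kb of a gene end in both libraries, in 1 of them or in neither, with the number of genes in parentheses. All 48 ribosomal protein genes carry an ERG-library peak and 40 also a Vector-library peak, whereas 9 of the 30 myeloid genes carry one in the ERG library alone.

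Of 22 ETS genes, 10 had an end peak in both libraries and 5 in the ERG library alone, with ELF4, SPIB, ELK3 and ETV3 those of largest difference. These 5 were 41.7% (15.2 to 72.3) of those without a Vector-library peak. Of 18 histone deacetylase genes, 9 had a peak in both and 7 in the ERG library alone, including HDAC10, HDAC3, SIRT7 and HDAC5. These 7 were 77.8% (40.0 to 97.2) of the 9 genes without a Vector-library peak, above the 22.5% of all genes, but so were 8 of 8 ribosomal protein genes (63.1 to 100%). The covered length of this list was not apart from random lists (median difference 1733.5 against 1616 bp, percentile 67.6). In the corepressor and coactivator list 20 of 27 had a peak in both, and BRD2 and CREBBP in the ERG library alone, 28.6% (3.67 to 71.0) of those without a Vector-library peak. With a 2.5 kb window ELF4, HDAC3, BRD2, PCNA and CDK6 counted as both. Cell cycle genes had 11 of 25 in both and 7 in the ERG library alone, including CCND3, PCNA, CDK6 and CCNE2. These 7 were 50% (23.04 to 77.0) of the 14 without a Vector-library peak, an interval just above 22.5%. They include PCNA and CDK6, which the 2.5 kb window moved to both. The 22.5% is over all genes, and the ribosomal protein genes reached 8 of 8, so this share is not particular to cell cycle genes. Apoptosis genes had 11 of 25 in both and 6 in the ERG library alone, including BCL2, BCL2L11, BID and TNFRSF10B, which is 42.9% (17.7 to 71.1) of those without a Vector-library peak.

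The control lists set the level of detection. All 48 ribosomal protein genes, which every cell transcribes, had an end peak in the ERG library, but 8 of them lacked one in the Vector library, RPS18, RPL23, RPS9 and RPL34 among them. BRD2 and RPS18 lie in the part of chromosome 6 where the genome build holds alternative copies. A missing Vector-library peak was therefore not evidence that a promoter lacked acetylation. Of the genes of other tissues, 0 of 20 neuronal and 0 of 20 fibroblast genes had an end peak in either library. 1 of 18 epithelial genes, MUC1 (chosen after its values were seen), had one in both, and TF and APOA1 of 20 liver genes had one in the ERG library alone. Near the neuronal genes SYN1 and GRIN1, the epithelial genes CLDN7 and ESRP1 and the fibroblast genes COL1A1 and MMP2, none with a peak at its own ends, ERG-library peaks within 50 kb covered 1093 bp (MMP2) to 4695 bp (CLDN7). MMP2 counted as ERG library alone with a 2.5 kb window.

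Single genes with the largest excess of covered length in the ERG library were PLCB3 (14227 against 4667 bp), SKI (10905 against 1875 bp), MAP3K11 (9507 against 589 bp), ANXA2R, AGPAT2, NACC2, the histone gene H4C6, UBR3, PGPEP1 and the histone gene H2AC18. Their excess ran from 7441 to 9560 bp. Covered length takes in any peak within 50 kb of a gene end, also those at neighbouring genes. AGPAT2, H4C6 and PGPEP1 had no gene-end peak in either library. AGPAT2 (9966 against 1354 bp) lies beside EGFL7 (8998 against 1354 bp), so its excess cannot be assigned to it. The largest excess in the Vector library was smaller by far. It was found at ELOA2 (1334 against 306 bp in the ERG library), PRKAB1, EAF2, CALCRL (732 against 0 bp), SAT2, FAM178B, FAM90A22, CCNI2, HIC2 and TP73, with differences (ERG minus Vector) from -1028 to -628 bp. EAF2 was the member of this group with a gene-end peak in the Vector library alone. PRKAB1 and HIC2 had one in both libraries and the others in neither. With a 2.5 kb window FAM90A22 joined EAF2 and ELOA2 counted as both.

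The 5 top-scoring unshared peaks of each library differed in their distance from coding genes. Those of the ERG library included 1 at ZNF566 (chromosome 19, 36489164 to 36490832) and others within 41.8 kb of LOC124903856, GRAP and PPIAL4H. Those of the Vector library lay far from coding genes, among them peaks at 496 kb from OR11H1, 844 kb from EMB, 1323 kb from POTEA and 1904 kb from WSB1. The strongest of them was at 25389790 to 25390104 on chromosome 17.

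Joining peaks away from gene ends gave 7694 domains in the ERG library and 2892 in the Vector library. Ranked by covered length, 11 of the top 20 of each library overlapped. Under the alternatives this number ran from 7, with peaks farther than 100 kb from a protein-coding gene left out, to 13 with the limited ERG list. Many of the top domains lay far from genes, since 9 of 20 in the ERG library and 13 of 20 in the Vector library lay over 100 kb from a protein-coding gene. The first of both was on chromosome Y from 56673320 to 56770143, with 21373 bp covered in the ERG library, followed by chromosome 1 from 143184623 to 143266929. The nearest genes of these were CDY1 and H3-7, and the others among the first 10 were nearest LOC102723475 (ribosomal RNA repeats), CCDC200, PLS3, ZNF337, LINC02798, FCGR2A (a tRNA gene cluster), UQCRFS1, SHCBP1, EMB and ZNF33B. CDY1 lay 31048 kb from its domain, LINC02798 3241 kb and UQCRFS1 2018 kb, whereas CCDC200 lay 2.7 kb away. Nearest genes therefore give a position only and do not assign a domain to a gene. Repeat annotation was not used here. Among the first 10 ERG-library domains, those overlapping coding genes were at SKI (chromosome 1, 2278885 to 2316031, 6644 bp covered against 1432 bp in the Vector library) and at EGFL7, an endothelial gene that hosts a microRNA (chromosome 9, 136644671 to 136665417, 6573 against 1057 bp). With the ERG list limited to the length of the Vector list the domains numbered 2749 and 2892.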

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

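A signal lay outside the data that the gene comparisons use, which are limited to chromosomes 1 to 22, X and Y. Of the ERG-library peaks 698, or 3.55% (95% interval 3.29 to 3.82), were on other sequences of the build, against 221 or 2.41% (2.11 to 2.75) of the Vector-library peaks. Alternative copies of parts of chromosome 6 held 207 ERG-library and 28 Vector-library peaks, while chromosome 6 itself held 960 and 416. In the major histocompatibility region of chromosome 6, which most of those copies represent, there were 33 and 5 peaks. The remaining other sequences held 491 and 193.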

How the results depend on the processing

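No paired analysis was possible because each group holds 1 library. The 3 thinned versions of the ERG list, the limit to peaks near coding genes and every alternative for fragments at shared peaks were chosen after seeing the data. Of 248 recomputed values 181 stayed within their limits, 40 moved beyond them, 13 list percentiles came inside the central 95% of random lists, 14 went outside it and 0 reversed. Most of the 181 were percentiles of single lists, 97 of 115 for covered length and 57 of 66 for fragments, tied lists included. All 8 alternatives of each overlap share and all 3 of each gene-end share moved beyond the counting interval of the main value. A percentile could count as reversed only where the list lay outside that range in the main setting. The 0 therefore does not show a stable direction for the other lists. For covered length, the globin list ran from percentile 8.90 to 97.0 under the alternatives. A single start site per gene, and the motif alternatives, were not run. The cause of the changes was not tested unless the setting itself gives it.

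The share of ERG-library peaks with no Vector-library peak was 71.3% with an overlap of 50% of the peak, 54.7% when a peak within 1 kb counted, 56.1% in the upper 50% of each list by score, 28.5% with the ERG list limited to the length of the Vector list, which makes both shares alike by construction, and 61.3% with 500 bp peaks. With the ERG library thinned to the Vector background it was 55.7%, thinned by the ratio at shared peaks 49.4%, and by that at strong shared peaks 47.0%. For Vector-library peaks with no ERG-library peak the values in the same order were 10.3%, 7.30%, 4.56%, 25.8%, 16.9%, 9.99%, 13.8% and 16.7%. The upper 50% by score holds by construction 9835 and 4580 peaks. The thinned ERG lists still held 18062, 15118 and 13920 peaks, although thinning could not bring in the loss of width that a shallower library would have.

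The share at gene ends of ERG-only, shared and Vector-only peaks was 34.0%, 68.8% and 19.0% with a 2.5 kb window, 53.5%, 72.4% and 36.3% in the upper 50%, and 43.9%, 70.9% and 33.4% with the limited ERG list. Genes with an end peak in 1 library alone numbered 1235 (ERG) and 734 (Vector) with the limited list. Those in the Vector library alone were 225 and 333 with the ERG library thinned by the ratio at shared and at strong shared peaks. Gene lists outside the percentile range for covered length were 1 of 23 with 10 kb, the upper 50% or the limited list, in place of 3. That list was iron handling (percentile 1.78), apoptosis (99.4) and erythroid transcription regulators (1.66) in turn, none of the 3 of the report. With 100 kb the heptad stayed outside, and the heme list (1.52) and the neuron control (99.2) went outside. With peak numbers the heptad and mast cell lists stayed outside and the erythropoietin list (98.0) went outside. Domains numbered 13699 and 7530 with gene-end peaks kept, and 2749 in the limited ERG list. The top 20 domains shared 7 when peaks farther than 100 kb from a protein-coding gene were left out. Weak sites were least often found in both libraries: 8.79% of ERG-library peaks with fewer than 20 fragments had a Vector-library peak.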

Other observations

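All tests in this part were chosen after the result was seen, as was the measure itself. At sites with a peak in both libraries, the fragments at the summit can be set against each other. Each Vector-library peak was paired with the overlapping ERG-library peak of most fragments, and a wide ERG-library peak could serve more than 1 pair. This pairing can raise the ratio, by an amount that was not measured. The summits of a pair lay a median of 67 bp apart. Over 8318 shared peaks the median ratio of fragments (ERG over Vector) was 2.09 (quartiles 1.69 to 2.53), and 160 (1.92%) had fewer fragments in the ERG library. The 14 members of the heme list had a median log2 ratio of -0.55 relative to the typical shared peak, 11 of them below 0, and 0 of 10000 matched random lists lay as low, where 0.55 of 11 lists would lie outside the range by chance. With fragments divided by the local background the list lay at percentile 4.1 with a median of -0.14, inside the central 95%. BLVRB, the biliverdin reductase gene, had 62 ERG-library and 64 Vector-library fragments, FECH, the last enzyme of heme synthesis, 51 and 41, PPOX 56 and 42, and ABCB10 54 and 41. The counting interval of these 4 lay below the typical ratio, that of UROD (145 and 48) above it. Over all 6023 genes, 3.29% had an interval below and 6.28% above. The globin genes HBG2 (37 and 48 fragments) and HBQ1 (21 and 22), the iron genes TFR2 (26 and 38) and ISCA2 (21 and 22), the membrane genes SLC2A1 (69 and 52) and SPTB (17 and 22) and the coactivator gene KAT2B (27 and 25) also had intervals below it, and the iron list lay at percentile 8.20. At TFR2 the local background was also lower in the ERG library (5.82 against 10.2 fragments), and the deposited folds, each of its own list, were 3.96 and 3.48.

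Besides UROD, intervals above the typical ratio were found among listed genes for HHEX (117 and 30 fragments), a blood and endothelial regulator, SLC18A2 (85 and 18), LYN (136 and 44) of the cytokine signalling list, the ETS gene ETV6 (172 and 58), the deacetylase genes HDAC6 (86 and 23) and SIRT4 (153 and 37), MED1 (61 and 14), BAD (129 and 37) and 5 ribosomal protein genes, RPL4, RPL19, RPLP2, RPS13 and RPS27A. Among 4890 genes with 60 or more fragments, the 10 lowest by fragments, not corrected for the local background, were TFR2, CDC16, HBG2, ACP5, CLCN7, ANAPC2, CCDC88B, VPS13D, BLVRB and MTOR. The highest was FRAT1 with 118 and 19 fragments.

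The first pattern weighed is the longer list of the ERG library. Greater depth alone would give shared peaks the ratio of the genome backgrounds, 1.44. The median at gene ends was 2.16 (quartiles 1.81 to 2.58). Depth was thus not the whole of it, unless the pairing of peaks raised the ratio that far, which was not measured. The local background at these peaks had a median ratio of 2.02, also above 1.44, so the excess over the local background was small. If no input library was used, this background can hold the peaks' own flanks. Shared peaks farther than 500 kb from a coding gene had a ratio of 1.44. A lower share of fragments in peaks in the Vector library may account for the rest: the ribosomal protein genes, which both libraries should carry alike, had a ratio of 2.27. A gain of acetylation at most promoters with ERG would give the same value, so the 2 cannot be told apart with 1 library per group.

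The second is the low ratio at heme genes. A copy-number difference of their chromosome segments would lower neighbouring peaks too. However, shared peaks from 10 kb to 1 Mb away had a median relative log2 ratio of 0.0827 (quartiles -0.09 to 0.17). At ABCB10 both the neighbours (-0.54) and its own peak (-0.66) lay low, so a copy-number difference is not excluded for that gene. The neighbours of TMEM14C (-0.28) and UROS (-0.21) also lay low, while the genes' own peaks (-0.04 and 0.29) were not low. Division by the local background ended the call (percentile 4.1), since the median moved from -0.55 to -0.14. With 1 added to both, the list lay at 0.76 with a median of -0.20. Under these measures 4 and 5 of the 11 lists lay outside the central 95%: the ETS (0.24 and 0.38) and erythroid membrane (0.71 and 0.415) lists lay lower than the heme list, and the deacetylase (98.9 and 99.1) and ribosomal protein (99.7 and 99.0) lists above, so the heme list did not stand alone. If no input library was used, the local background and the peak cannot be told apart here. Both would then be measured on the same reads, and the background may hold the peak's own flanks. Whether an input library was used is not given. A difference at heme genes that goes with ERG itself was not tested and stays open.

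The third is the 822 Vector-library peaks with no ERG-library peak. Of those on chromosomes 1 to 22, X and Y, 18.6% (16.0 to 21.5) lay farther than 500 kb from a protein-coding gene against 8.20% of shared ones, as fragments from repeated sequence would give. They had a median of 15 fragments at the summit against 28, as peaks close to the calling threshold would have. Both may contribute, and a loss of acetylation with ERG at some of these sites was not tested and stays open.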
